A study of Homo sapiens with 9 samples.

How the data were processed

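DNA methylation was measured by digital restriction enzyme analysis of methylation (DREAM) in 9 libraries of genomic DNA from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels' protocols, cells were transfected with an empty pIRES plasmid or with plasmids for the TET1 forms called TET1-ALT and TET1-FL, and DNA was taken 4 days later. Each group held 3 libraries. The labels number the replicates and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

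In DREAM, DNA is cut first with SmaI, which cuts CCCGGG only where the CpG is unmethylated, and then with XmaI, which cuts the remaining methylated copies and leaves a different end. Per the series' design text in the labels, the authors took methylation at each CCCGGG site as the share of methylated reads among all reads and then corrected it for enzyme efficiency with spiked-in standards. The deposited values are in percent, per the file headers and the range of the values, which held 0 exact zeros and 0 values of exactly 100. Per the labels' protocols, fragments were size selected and amplified with 18 PCR cycles. Sites were named on hg19, per the submitters' processing notes and the file headers. The aligner, its settings and the methylation caller are not given in the sources used here, and neither is a sequencing batch or date.

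Per the labels, a value required at least 20 reads. The read depth behind each value is otherwise unknown, so no interval that needs depth is given. No source used here names molecular identifiers. The table listed 382289 sites, of which 75645 had a value in at least 1 library and 59751 had a value in all 9 libraries. The 59751 complete sites were used throughout, and 18 sites on 8 sequences outside the genome, taken here as spiked-in standards, were kept apart, while the labels mention 5 standards without naming them.

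From the percent values, limma was fitted per site to all 9 libraries with a mean per group and no replicate term, with an intensity trend and robust moderation, and p-values were adjusted by the Benjamini-Hochberg method over all sites of a comparison. A site was called at an adjusted p under 0.05. The planned count model could not be used because the table held percentages, and the fallback fixed for that case was limma on the percentages. Mean methylation per library was compared by a two-sided exact permutation test, for which 3 libraries against 3 give 20 assignments and a p no lower than 0.1. The range of all pairwise differences between libraries of both groups is an exact 90% interval for a constant shift and is given beside the main differences. Sites were classed by their mean over all 9 libraries as under 5%, 5 to 20%, 20 to 80%, 80 to 95% and over 95%. Local density was the number of other listed CCCGGG sites within 1000 bases.

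These tests, the classes and most alternative settings were fixed before the data were examined. Means over 100 kb windows with at least 5 sites of 20 to 95% mean methylation, tested with the same limma model, the density classes, the comparisons by chromosome and the tests on held-out libraries were added after seeing the data. The scripts were tested on simulated data. With TET1-FL compared against the empty vector over 59751 sites and 50 sites changed at each size, the site test recovered 0% of sites changed by -5 points, 28% at -10, 66% at -20 and 90% at -30. Over 1755 windows it recovered 18% of windows changed by -2 points and 88% at -4. For the comparisons that share the empty vector libraries, unchanged groups were simulated 20 times, and 10 times more with lists of the real lengths, which was also added after seeing the data.

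The rule fixed for named genes took, among called sites with a difference of at least 10 points, non-overlapping libraries and a transcription start within 1000 bases, the largest falls and rises. It could not be applied, since no site was called and no hg19 annotation was used here. The table gives no gene names, and the gene table at hand is of another build. Gene lists, promoter and exon classes, CpG islands and sites in TET1 were therefore not analysed here. In their place the text names the 12 called windows with the largest falls and all with rises. It names sites by the size of the difference, the 3 most negative and 6 most positive between TET1-FL and the empty vector and 2 each way in the other comparisons. These come from sites whose 3 libraries lay outside the range of the other group and whose group means were at least 10 points apart, with at most 1 site per 1000 bases. The windows and the sites were both chosen after the values were seen.

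Alternatives covered a replicate block, sites measured in at least 2 libraries per group, a log2((percent+1)/(101-percent)) scale, limma without trend and robust moderation, only the 2 groups compared, centring on sites of 80% or more, minimum differences of 10 and 20 points, autosomes, sites of 20% or more, medians, classes by the empty vector mean and leaving out each library. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.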

Results

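The series measured DNA methylation at CCCGGG sites in HEK293T cells 4 days after transfection with an empty vector, TET1-ALT or TET1-FL. TET1 is a dioxygenase that oxidises 5-methylcytosine, a step towards loss of the methyl mark. Its full-length form carries a CXXC domain, which binds unmethylated CpG-rich DNA, and the series' title concerns an isoform without that domain. Each group had 3 libraries. A value was present at 66466, 66389 and 61549 sites in the empty vector libraries, at 68830, 69301 and 69739 in TET1-ALT and at 66010, 69784 and 72340 in TET1-FL. Read depth per site is unknown beyond the minimum of 20 reads in the labels. The values used here are methylation percentages only. They do not show oxidised cytosine separately, nor how much of each TET1 form the cells made.

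Methylation of the 59751 sites measured in all 9 libraries was distributed between an unmethylated and a methylated part. Sites under 5% numbered 22785 (38.1%), and 59.0% of them had at least 3 other CCCGGG sites within 1000 bases. Sites of 20 to 80% numbered 14880 and sites of 80 to 95% numbered 13308, with 28.4% and 27.8% at that density. A further 3488 sites lay at 5 to 20% and 5290 over 95%. The median standard deviation between replicates was 2.87 points for sites of 20 to 80%, 2.01 points for sites of 80 to 95% and 0.107 points for sites under 5%. Pearson correlations across sites, which are not independent replicates, were 0.995 to 0.997 both within and between groups.

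The first comparison asked how full-length TET1 changes methylation relative to the empty vector. Methylated sites had lower methylation in TET1-FL across the genome. Sites of 20 to 80% averaged 54.3% ± 0.357 (SD, n = 3) in TET1-FL and 56.1% ± 0.389 (SD, n = 3) with the empty vector, a difference of -1.84 percentage points with pairwise differences from -2.49 to -1.08. Sites of 80 to 95% averaged 88.1% ± 0.22 against 89.2% ± 0.279, a difference of -1.19 points. Sites over 95% differed by -0.349 points, sites of 5 to 20% by -0.726 points and sites under 5% by -0.072 points. In each of these 5 classes the 3 TET1-FL libraries lay below the 3 empty vector libraries. Over all sites the means were 42.6% ± 0.137 and 43.4% ± 0.161, a difference of -0.822 points (pairwise range -1.08 to -0.513). The exact permutation p was 0.1 for all sites and for every class, the smallest that 3 against 3 libraries allow, so none of these differences could pass 0.05.

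**Figure D1:**
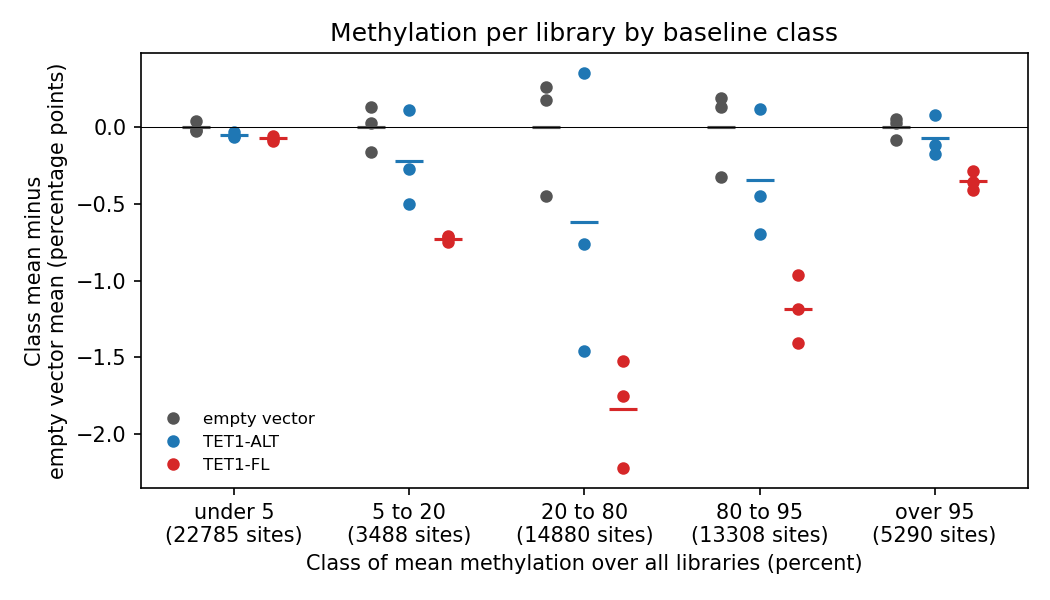
Mean methylation of each library minus the empty vector mean, in percentage points, for 5 classes of sites. Points are libraries and bars are group means. At 20 to 80% the TET1-FL mean lies -1.84 points from the empty vector mean, and 1 TET1-ALT library lies above all empty vector libraries.

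The lower level in TET1-FL was present on each autosome and on chromosome X. For the 28189 sites of 20 to 95%, TET1-FL libraries lay below the empty vector libraries without overlap on 23 of 23 chromosomes. The difference ranged among autosomes from -1.82 points on chromosome 20 to -1.29 points on chromosome 5, and chromosome X had -0.933 points. Sites with 0 to 2 neighbouring CCCGGG sites differed by -1.57 points, sites with 3 to 5 by -1.44 points and sites with 6 or more by -1.24 points. The last and first of these were 0.333 points apart (-0.529 to 0.782, exact permutation p = 0.2), with overlapping libraries, so no trend with density was established. Their empty vector means also differed, at 67.7% and 72.1%.

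At the level of 100 kb windows, 92 of 1759 windows changed between TET1-FL and the empty vector in limma at an adjusted p under 0.05. Of these, 89 fell and 3 rose, on 21 chromosomes. The windows that fell had a median difference of -3.49 points (-6.10 to -2.43), and 1626 of all 1759 windows (92.4%) had a lower mean in TET1-FL. The largest fall was on chromosome 20 from 600001 to 700000 (hg19), where 5 sites averaged 67.1% ± 1.16 with the empty vector and 61.0% ± 0.527 in TET1-FL (limma difference -6.10, SE 0.851, adjusted p = 0.0113). On chromosome 17 from 15800001 to 15900000 the mean of 6 sites went from 75.4% ± 0.853 to 69.7% ± 2.75 (limma adjusted p = 0.04996). Chromosome 22 held falls at 47100001 to 47200000, from 70.0% ± 0.950 to 64.4% ± 1.77, and at 29600001 to 29700000, from 80.2% ± 0.576 to 74.8% ± 1.55 (both limma adjusted p = 0.0358). On chromosome 8 the window from 22800001 to 22900000 fell from 79.9% ± 2.31 to 74.5% ± 1.67, and that from 144200001 to 144300000 fell from 74.7% ± 1.36 to 69.7% ± 1.65. Falls on chromosome 10 were at 125900001 to 126000000 (69.5% ± 2.24 to 64.5% ± 1.21) and at 71700001 to 71800000 (83.0% ± 1.85 to 78.3% ± 1.22). The window on chromosome 1 from 205400001 to 205500000 fell from 49.3% ± 1.29 to 44.6% ± 0.684. The other falls among the 12 largest were on chromosome 11 from 128700001 to 128800000 (85.9% ± 1.22 to 80.7% ± 2.28), on chromosome 16 from 67200001 to 67300000 (68.5% ± 1.10 to 63.7% ± 1.29) and on chromosome 20 from 22500001 to 22600000 (69.2% ± 0.602 to 64.6% ± 0.592).

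The 3 windows that rose in TET1-FL were on chromosomes 8 and 21. The rise on chromosome 8 from 48600001 to 48700000 was from 46.0% ± 3.23 to 53.6% ± 1.27 over 8 sites (limma difference 7.69, SE 1.51, adjusted p = 0.0358). On chromosome 21 the window from 9800001 to 9900000 rose from 42.1% ± 3.13 to 47.9% ± 1.61 over 11 sites, and on chromosome 8 the window from 600001 to 700000 rose from 53.5% ± 1.11 to 58.0% ± 0.844 over 5 sites (both limma adjusted p = 0.0476). The TET1-ALT means of these windows were also above the empty vector, at 50.3%, 45.8% and 57.3% in the same order. Empty vector replicate 1 was the lowest library in each. Without it 0 rises and 2 falls were called, beside 3 and 89. Leaving out TET1-FL replicate 1, 2 or 3 or TET1-ALT replicate 2 also gave 0 rises, so this loss is not particular to empty vector replicate 1. The count of 92 windows rests on single libraries, including TET1-ALT libraries, which take part in the choice of sites and in the shared estimate of spread. With sites and windows kept as chosen, it was 2, 3 and 50 without empty vector replicate 1, 2 or 3, then 0, 4 and 1 without TET1-FL replicate 1, 2 or 3, and 86, 1 and 24 without TET1-ALT replicate 1, 2 or 3. All 92 kept their direction each time, which carries little information. These windows were chosen for their difference in the same libraries, and leaving out a TET1-ALT library does not alter that difference. With libraries centred on sites of 80% or more, 1 window was called.

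**Figure D2:**
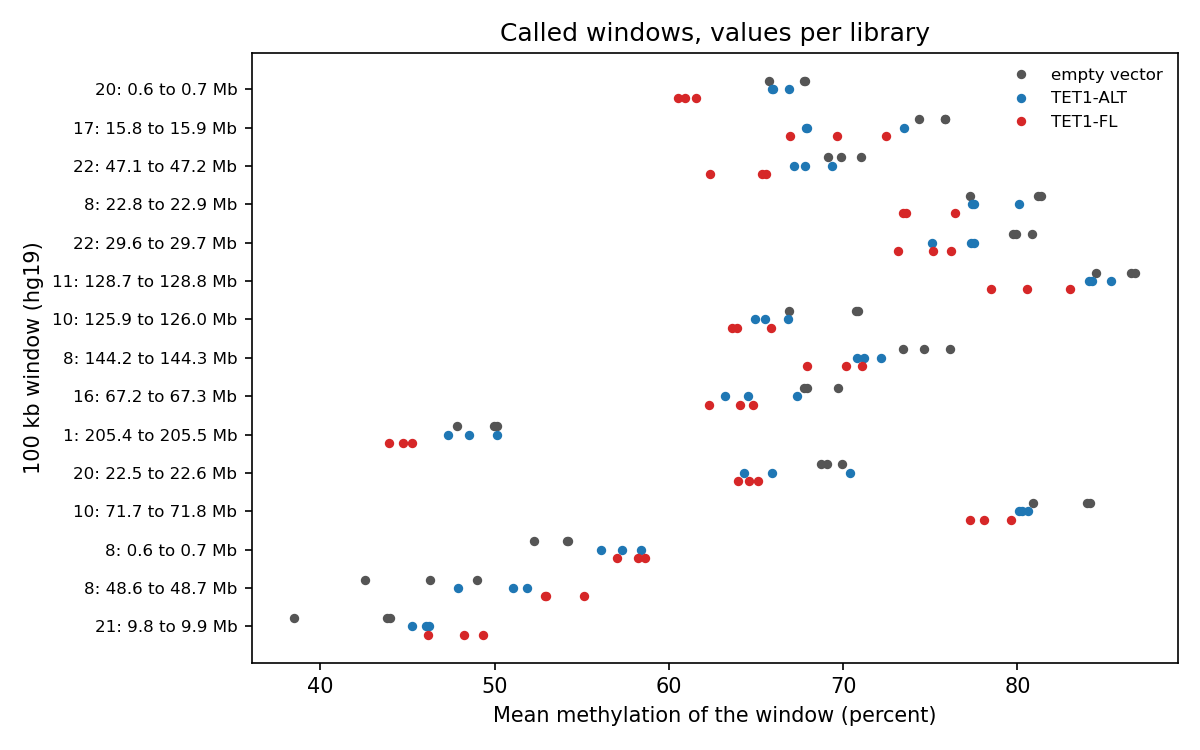
Mean methylation in percent (horizontal axis) of the 12 windows with the largest falls and the 3 windows with rises between TET1-FL and the empty vector, with hg19 positions on the vertical axis. Points are the 3 libraries of each group. In the uppermost window the empty vector mean is 67.1% and the TET1-FL mean 61.0%.

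Single sites did not pass the site test. In limma 0 of 59751 sites were called between TET1-FL and the empty vector, and the smallest adjusted p was 0.0843. At an unadjusted p under 0.05 there were 6471 sites, 5808 lower and 663 higher in TET1-FL, where chance gives 2988. The 3 TET1-FL libraries lay below the empty vector range at 8900 sites (14.9%) and above it at 1271 sites (2.13%), where chance gives 10% for both directions together. Of these, 191 lower and 70 higher sites had group means at least 10 points apart. Among the lower ones, the site on chromosome 22 at 37710110 had 85.2% ± 4.28 with the empty vector and 62.5% ± 15.0 in TET1-FL (difference -22.7, and -14.6 without TET1-FL replicate 1). The site on chromosome 13 at 64416817 had 87.5% ± 2.92 and 66.1% ± 21.4 (difference -21.4, and -9.12 without TET1-FL replicate 3), and that on chromosome 12 at 266641 had 66.6% ± 6.25 and 45.9% ± 8.00. The difference of such lower sites was mostly not seen in libraries that took no part in choosing them, where it averaged -2.38 points against -1.77 at sites of matched methylation. Among the higher ones, the site on chromosome 8 at 48650351 had 22.8% ± 15.7 and 57.4% ± 1.69, with TET1-ALT at 39.8% ± 7.28. The site on chromosome 10 at 3111356 had 28.2% ± 13.6 and 48.7% ± 2.18 (difference 20.6, and 12.7 without empty vector replicate 1), and the one on chromosome X at 129066546 had 8.93% ± 5.05 and 28.6% ± 3.73. Next came chromosome 1 at 38511922 (17.9% ± 4.07 and 37.4% ± 6.09) and chromosome 11 at 8290260 (10.9% ± 4.57 and 29.7% ± 3.58) and at 9113235 (68.6% ± 10.5 and 87.2% ± 0.82). Empty vector replicate 1 was the lowest of the 9 libraries at each of these 6 sites, while over the 70 higher sites replicates 1, 2 and 3 were the lowest empty vector library at 30, 12 and 28. The TET1-ALT mean was also above the empty vector mean at 67 of the 70 higher sites, and below it at 186 of the 191 lower ones. In held-out libraries such higher sites differed by 1.42 points against -1.69 at matched sites. With libraries centred on sites of 80% or more, 17525 sites were called, 592 lower and 16933 higher, and 97.9% of the higher ones were sites under 5%, to which the centring adds a difference of 0.777 points.

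The comparison of TET1-ALT with the empty vector addressed the isoform named in the series' title. Methylated sites averaged less in TET1-ALT than with the empty vector, but by less than the spread between libraries. Sites of 20 to 80% averaged 55.5% ± 0.914 in TET1-ALT, a difference of -0.620 points from the empty vector with pairwise differences from -1.72 to 0.802 (exact permutation p = 0.4, n = 3 each) and from -1.11 to -0.202 when each library was left out. Sites of 80 to 95% differed by -0.343 points with pairwise differences from -0.888 to 0.438 (exact permutation p = 0.2, -0.573 to -0.166 when each library was left out). Sites over 95% differed by -0.069 points with pairwise differences from -0.227 to 0.164 (exact permutation p = 0.5, -0.143 to -0.016 when each library was left out). Over all sites the mean was 43.1% ± 0.346, a difference of -0.269 points (-0.686 to 0.292, exact permutation p = 0.3). TET1-ALT replicate 1 stood apart at 43.5%, inside the empty vector range, with replicates 2 and 3 at 43.04% and 42.8%. Without replicate 1 the difference over all sites was -0.456 points, and without replicate 3 it was -0.116 points.

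Sites of low methylation were the class in which the TET1-ALT libraries lay below all empty vector libraries. Sites under 5% averaged 0.517% ± 0.017 in TET1-ALT and 0.566% ± 0.033 with the empty vector, a difference of -0.049 points (exact permutation p = 0.1, n = 3 each, -0.061 to -0.030 when each library was left out). Pairwise differences were from -0.101 to -0.0074 points. The libraries were apart at those with 0 to 2 neighbours (-0.079 points) but not at those with 3 to 5 (-0.035 points, exact permutation p = 0.3) or 6 or more (-0.0088 points, exact permutation p = 0.8). On chromosomes, sites of 20 to 95% had a lower mean on 23 of 23, from -0.736 points on chromosome 20 to -0.223 points on chromosome 18 among autosomes, but library ranges were apart on 0 of them. In limma 0 of 59751 sites and 0 of 1759 windows were called, with smallest adjusted p of 0.247 for sites. At an unadjusted p under 0.05 there were 4312 sites (3279 lower, 1033 higher) and 130 windows, and 1796 of the lower sites were under 5%. The balance turned with libraries centred on sites of 80% or more (1210 lower, 1716 higher). That centring shifts all sites of a library by 1 constant, also those under 5%, so the turn does not show how methylated sites moved. Without TET1-ALT replicate 3 there were 1822 lower and 1157 higher sites and 88 windows, and without TET1-ALT replicate 1 there were 209 windows. Libraries were separate, with group means 10 points or more apart, at 106 lower and 58 higher sites. Among the 106 lower ones, those on chromosome 3 at 133786821 (69.8% ± 7.49 with the empty vector, 48.4% ± 0.71 in TET1-ALT) and on chromosome 17 at 19770860 (33.8% ± 1.94 and 13.8% ± 4.56) had the most negative differences. Among the 58 higher ones, those on chromosome 1 at 2368659 (27.4% ± 6.36 and 49.3% ± 10.7) and on chromosome 10 at 3111356 (28.2% ± 13.6 and 49.6% ± 6.20) had the most positive, the latter 21.5 points and 13.6 without empty vector replicate 1. At sites lower in TET1-ALT by at least 10 points in the libraries used to choose them, where the chosen difference averaged -13.0 points, held-out libraries differed by -1.16 points against -0.584 at matched sites. For higher sites so chosen (13.04 points) they differed by -0.0397 points against -0.581.

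Full-length TET1 and the TET1-ALT form were then compared with each other. Methylated sites were lower in TET1-FL than in TET1-ALT. The difference was -1.22 points at sites of 20 to 80% (pairwise -2.58 to -0.069), -0.842 points at 80 to 95% and -0.281 points over 95%, with library ranges apart in each of these classes. Without TET1-ALT replicate 1 the difference at 20 to 80% was -0.727 points. Over all sites it was -0.553 points (-1.08 to -0.123). The exact permutation p was 0.1 for these values, the smallest possible. Sites under 5% differed by -0.023 points with overlapping ranges (exact permutation p = 0.3). On chromosomes the TET1-FL mean was lower on 23 of 23, with ranges apart on 20. In limma 0 of 59751 sites and 0 of 1759 windows were called between the forms, with 3319 sites (2664 lower, 655 higher in TET1-FL) and 257 windows at an unadjusted p under 0.05. With libraries centred on sites of 80% or more these were 1139 lower and 16899 higher sites and 126 windows, and without TET1-ALT replicate 1 there were 130 windows. The centring also shifts unmethylated sites by a constant, and how many of the 16899 sites were under 5% was not counted. Libraries were apart, with group means differing by at least 10 points, at 63 lower and 26 higher sites. The site on chromosome 16 at 31549142 had 54.1% ± 6.16 in TET1-FL, 74.1% ± 5.46 in TET1-ALT and 67.0% ± 2.17 with the empty vector, and that on chromosome 11 at 120592529 had 16.9% ± 11.2, 34.7% ± 1.96 and 27.0% ± 12.6. Higher in TET1-FL were the sites on chromosome 3 at 185379490 (64.25% ± 8.38, 42.2% ± 8.71 and 59.7% ± 8.46) and on chromosome 22 at 17517404 (66.1% ± 6.28, 45.9% ± 1.22 and 56.7% ± 11.6).

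**Figure D3:**
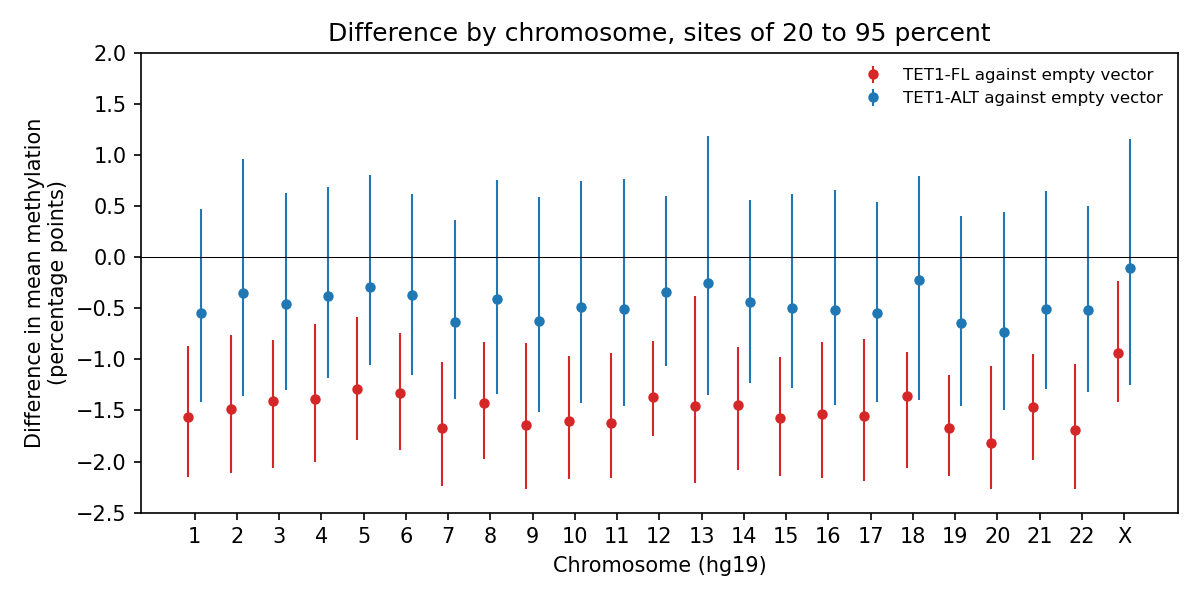
Difference in mean methylation from the empty vector, in percentage points, by chromosome (hg19) for sites of 20 to 95%. Points are differences of group means and bars span all pairwise differences between libraries. TET1-FL bars lie below 0 on 23 of 23 chromosomes and TET1-ALT bars cross 0 on each.

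The comparisons of TET1-FL and of TET1-ALT with the empty vector share the empty vector libraries, which by itself makes their differences agree. Of the 89 windows that fell in TET1-FL, 86 had a lower mean in TET1-ALT, with a median difference of -1.59 points, where 1298 of all 1759 windows (73.8%) were lower in TET1-ALT, with a median of -0.505. In 10 simulations of unchanged groups with the same controls, the 89 windows of lowest p among those lower in TET1-FL were taken. Of these, 73 to 81 had a lower mean in TET1-ALT, with a median of -0.953 points, and no general shift was simulated. Their median difference in TET1-FL was -1.87 points, beside -3.49 for the real windows. The TET1-ALT medians are therefore not at like TET1-FL differences. Over the 28189 sites of 20 to 95% the differences from the empty vector had a correlation across sites of 0.603, beside 0.500 for simulated unchanged groups with the same controls. Their covariance was 5.17, beside 3.82 simulated, an excess of 1.35. The simulations gave each site a single spread pooled over all groups. A larger spread of the empty vector libraries could therefore also give an excess, here and in the counts that follow. The number of sites called in both comparisons was 0 in limma. At an unadjusted p under 0.05, 2159 sites were lower in both, beside 319 for independent lists and 1371 to 1434 for simulated unchanged groups with lists of the same lengths (5808 and 3279 sites). For sites higher in both the count was 203, beside 11.5 for independent lists and 178 to 203 simulated (lists of 663 and 1033 sites). For differences that share no library, after removing the mean at each methylation level, the mean correlation across sites was 0.025 between TET1-FL and TET1-ALT, 0.036 between TET1-FL libraries and 0.016 between TET1-ALT libraries. The mean covariance between TET1-FL and TET1-ALT was then 0.601, less than the excess of 1.35 over the simulation.

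Sequences outside the genome, taken here as spiked-in standards, were measured in the same libraries. The table has 8 of them, while the labels mention 5 standards and do not name them, so not all 8 need be standards. Library means over their 18 sites were between 44.0% and 44.2%. Which of these sites served for the efficiency correction is not given in the sources used here. For any that did, close values could follow from the correction itself. The 6 sequences of 20 to 80% differed between TET1-FL and the empty vector by 0.073 points on average (SD over sequences 1.21), with 3 lower and 3 higher, from -1.40 to 1.63 points. In TET1-ALT these 6 differed from the empty vector by -0.012 points on average (SD 0.857). Libraries of TET1-FL and the empty vector were apart at 1 of the 8 sequences, where TET1-FL differed by -0.912 points. The sequence at 7.04% with the empty vector differed by -0.390 points in TET1-FL and -0.457 in TET1-ALT, with overlapping libraries. For the sequence at 99.0% these were -0.120 and 0.082 points, also with overlap.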

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

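The windows and their settings, and the counts at an unadjusted p, were tested only after the results were seen. The count of 0 called sites in each comparison was the same in every setting run except centring on sites of 80% or more, which gave 17525 for TET1-FL against the empty vector, 16933 of them higher, mostly unmethylated sites to which it adds a constant, and 592 lower, for which the cause was not tested. For mean methylation of TET1-FL against the empty vector, main difference -0.822 points, sites of 20% or more gave -1.34, by construction with fewer unmethylated sites, and the median over sites gave -1.62, for which the cause was not tested. For TET1-FL against TET1-ALT these were -0.919 and -1.20. All mean differences kept their direction when each library was left out (-0.914 to -0.749, -0.456 to -0.116 and -0.706 to -0.365 for TET1-FL against empty vector, TET1-ALT against empty vector and TET1-FL against TET1-ALT). Classes by the empty vector mean gave -1.72 points at 20 to 80% for TET1-FL, and over 95% -0.714 instead of -0.349, while classes by the TET1-ALT mean, added after seeing the data, gave -0.356.

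The 92 of 1759 windows between TET1-FL and the empty vector became 15 of 861 with windows of 10 kb, 20 of 1170 with 1 Mb and 161 of 501 with 5 Mb. They became 2 of 3149 with at least 3 sites per window, 200 of 607 with at least 10 sites and 3 of 4035 with sites of every methylation level. With the 1759 windows kept, there was 1 after centring and 0 to 86 when each library was left out. For TET1-ALT against the empty vector 1 window was called with at least 3 sites per window. For TET1-FL against TET1-ALT 1 was called with 1 Mb windows, 1 without trend and robust moderation, and 0 to 1 when each library was left out. The cause was not tested. At an unadjusted p under 0.05, a separate fit to the 33479 sites of 20% or more gave 3610, 1777 and 2068 sites. The main fit gave 6471, 4312 and 3319 of 59751 sites, so these counts are over unlike numbers of sites. Of the main counts, 2036, 2132 and 675 were sites under 5%, which the separate fit leaves out. Centring, which also shifts unmethylated sites, gave 21151 at this threshold for TET1-FL against the empty vector and 18038 against TET1-ALT.

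There was no sign that replicate numbers pair the samples. Same-numbered libraries had deviations correlated at -0.0151 to 0.02, and 1 of 9 libraries correlated best with its own number in both other groups. Even differences between TET1-FL libraries that share no library correlated at only 0.036 on average, so a weak pairing could go unseen. With the replicate block, 0 sites were called in each comparison, 17 windows for TET1-FL against the empty vector, and mean differences were -0.822, -0.269 and -0.553 points (exact sign-flip p = 0.25, 0.5 and 0.25, where 0.25 is the smallest possible). Settings that need read depth or counts (minimum of 50 or 100 reads, dispersion, depth weights, unadjusted counts) and those of the gene lists were not run, because the values are percentages without depth and no hg19 annotation was used here. Depth limits the precision of single sites to an unknown degree.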

Other observations

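All tests in this part were chosen only after the results they bear on were seen. The window with the largest rise in TET1-FL held a pair of sites with large differences. On chromosome 8 the sites at 48650151 and 48650351 (hg19), 200 bases apart, had 27.4% ± 15.4 and 22.8% ± 15.7 (SD, n = 3) with the empty vector, 46.3% ± 7.91 and 39.8% ± 7.28 in TET1-ALT, and 61.3% ± 1.502 and 57.4% ± 1.69 in TET1-FL. The next measured site at 48650809 had 4.41% ± 6.16, 9.36% ± 4.09 and 16.4% ± 3.43, while the site at 48650978 had 21.6% ± 4.53, 21.4% ± 2.36 and 22.6% ± 1.00. On chromosome 21 the sites at 9826364 and 9826484 had 28.2% ± 8.65 and 28.5% ± 8.66 with the empty vector and 46.0% ± 2.22 and 46.6% ± 2.33 in TET1-FL, and the nearby sites at 9825895, 9826093 and 9826541 differed by 7.71, 11.98 and 12.9 points, whereas those at 9826147 and 9826307 differed by -1.01 and -0.940 points. Without empty vector replicate 1 the differences were 3.46 at 9825895, 7.68 at 9826093, 12.8 at 9826364, 13.1 at 9826484 and 12.1 at 9826541, and on chromosome 8 they were 26.1 at 48650151 and 26.6 at 48650351. Empty vector replicate 1 was the lowest of the 9 libraries at all 6 sites with the largest rises in TET1-FL, on chromosomes 1, 8, 10, 11 and X, for example 6.87% at 48650351, where replicates 2 and 3 had 38.2% and 23.5%. Over all 70 sites higher by at least 10 points, replicate 1 was the lowest empty vector library at 30, replicate 3 at 28 and replicate 2 at 12.

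Chromosome X differed less than autosomes of matched methylation. Its 784 sites of 20 to 95% differed between TET1-FL and the empty vector by -0.933 points, while 10000 draws of autosomal sites in the same 5-point bins of methylation averaged -1.68 (95% of draws from -1.91 to -1.46), and 0 of the draws were as high. For TET1-ALT the values were -0.106 points and -0.577 (0 of 10000 draws as high). These draws measure the spread over sites, not over libraries.

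The lower methylation of methylated sites in TET1-FL may be biological or technical. Less incomplete digestion by SmaI would lower sites of 5 to 20% by more points than sites of 20 to 80%, but the ratio was 0.396 (0.323 to 0.492 over the TET1-FL libraries). Unmethylated DNA mixed into the libraries would lower sites over 95% the most, but their difference was 0.190 times that at 20 to 80% (0.159 to 0.233), and with classes by the empty vector or the TET1-ALT mean it was 0.414 or 0.193 times. A single odds factor per library, as an error in the efficiency correction could leave, predicts equal shifts in log2 odds, but sites of 80 to 95% shifted by -0.0688 beyond sites of 20 to 80% (-0.0853 to -0.0484, exact permutation p = 0.1, libraries apart). Depth and library batch, for which no values were at hand, and an effect of full-length TET1 stay open and untested.

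Sites that were lower in TET1-FL by at least 10 points may be selected noise on top of the general shift. When sites were chosen on 2 libraries of each group, their chosen difference averaged -13.1 points, and the held-out libraries gave -2.38 points, which was -0.610 points from sites of matched methylation (-1.09 to -0.125 over 9 choices of held-out libraries). Of these held-out differences 17.5% were 10 points or more below 0, against 5.54% of matched sites, and 7.12% were 10 points or more above 0, against 2.47%, so large differences were more frequent on both sides.

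Of sites higher in TET1-FL by at least 10 points, selection may account for most of the difference but is unlikely to account for all of it if these sites share the general shift. An empty vector library left out of the choice lay a median of 6.42 to 8.65 points above the other 2. That test was run first. With 1 library of each group held out, the held-out difference of 1.42 points (-0.0982 to 2.39 over 9 choices) lay 3.12 points above matched sites (2.18 to 4.02), with 18.6% at 10 points or more against 2.34% of matched sites, and 12.3% at -10 points or less against 5.17%. With empty vector replicate 2 or 3 held out, replicate 1 did not enter the held-out difference. That difference still lay 2.18 to 4.02 points above matched sites. At sites so chosen this argues against low values of replicate 1 alone, if these sites share the general shift. For the 70 sites chosen on all libraries, low values of empty vector replicate 1 alone stay open. The mean difference over the 70 sites was 13.7 points and 13.2 without it, beside 13.1 without replicate 3. All empty vector libraries took part in choosing these sites, so a large remaining difference was nearly fixed in advance. The count of sites at which replicate 1 was lowest, tried before, could not decide either.

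A hypothesis that the CXXC domain directs full-length TET1 to CCCGGG-dense DNA would make TET1-FL minus TET1-ALT more negative at dense sites. At sites with 6 or more neighbours it was instead 0.300 points less negative than at sites with 0 to 2 (-0.158 to 0.604, exact permutation p = 0.3), with overlapping libraries, so these data could not decide it. All CCCGGG sites measured here lie at 1 motif, which limits what density can show.

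The 6 libraries of each comparison can be split in 10 ways, the real one included, too few for a share under 0.05. For TET1-FL against the empty vector the real split gave 6471 sites at an unadjusted p under 0.05 and the highest other 3073, with 1 of 10 splits as large, and 92 called windows against 0, again 1 of 10, with 624 windows at an unadjusted p under 0.05 against 156 (1 of 10). For TET1-ALT the values were 4312 sites and 3523 (1 of 10), 0 called windows and 0 (10 of 10), and 130 windows at an unadjusted p under 0.05 and 245 (2 of 10). For TET1-FL against TET1-ALT they were 3319 sites and 3666 (3 of 10), 0 called windows and 1 (10 of 10), and 257 windows at an unadjusted p under 0.05 and 174 (1 of 10).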
